A study of Mus musculus with 12 samples.

How the data were processed

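Mouse embryonic stem cells of a cross between C57BL/6 and CAST strains (BL6xCAST in the labels) carried 1 of 2 synthetic constructs integrated on chromosome X, and open chromatin was measured by ATAC-seq, in which Tn5 transposase inserts sequencing adapters into accessible DNA. The construct synHPRT1 holds sequence of human HPRT1, the gene of a purine salvage enzyme, and synHPRT1R holds its reversed counterpart. Per the labels' protocols, cells grew on gelatin in a medium made mostly of 2i medium with LIF, were lysed and tagmented, and the DNA was amplified by PCR. There were 12 libraries, 6 per genotype, made of 2 clones with 3 replicates per clone. Groups and replicate numbers came from the sample titles. The labels do not say whether replicates of a clone came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

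The submitters' processing notes name bcl2fastq 2.20, Bowtie2 2.2.9, SAMtools 1.9, deepTools 3.5.0 and MACS2 2.1.0 and the builds GRCm38 and mm10. How these tools were run, whether reads were shifted for the Tn5 overhang, how duplicates and multi-mapping reads were treated and whether a blacklist was applied are not given in the sources used here. Each sample has 1 peak list, so peaks were called per library and not on pooled samples. The authors' deposited lists have no header and follow the MACS2 narrowPeak layout. The deposited score is an integer equal to 10 times the −log10 q-value, rounded down, in at least 99.98% of the peaks of each library. The deposited fold is the ratio of the summit pileup to the local background, with 1 added to both. The deposited −log10 p-value and −log10 q-value are those of the same summit, and the lowest −log10 q-value in any list was 1.30, so the authors kept peaks at q under 0.05. The last deposited column is the offset of the summit from the peak start. No read counts were used, and a fold or q-value served only to describe, rank or filter peaks within its own list, except where the summit pileup was recovered as described below.

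Peak positions are in GRCm38 coordinates for the mouse chromosomes. The synHPRT1 lists also hold peaks on a custom sequence whose name gives HPRT1 in the BigIN vector backbone, here called the construct sequence, and positions on it count from its own start. The synHPRT1R lists hold no peak on any sequence other than the mouse chromosomes and the mitochondrial genome. The peak names of every list are numbered from 1 with 104 to 165 numbers skipped, all between chromosomes and none inside a chromosome or before the first listed peak, and peaks on any sequence skipped there were not analysed here. The length of the construct, the place of HPRT1 within it and the position of the integration site on chromosome X are not given in the sources used here. Mouse genes came from a RefSeq gene table of assembly GRCm38.p6, which gives the outermost start and end of each gene without strand, exons or transcripts. The promoter measure planned from transcription start sites was therefore replaced by a peak within 1 kb of either annotated gene end. Gene ends that include distal transcript models can lie away from the promoter in use, so a second measure, any peak from 1 kb before to 1 kb after the gene, was added after the data were seen. Whether a peak is exonic or intronic was not determined.

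Depth was read from the lists themselves. In a peak whose local background equals the genome-wide background, the folds move in equal steps of 1 read, and the spacing of the 12 commonest folds gave the genome-wide background pileup of each library. Between 46.1% and 57.1% of the peaks of a library lay on such steps within 0.002, and for at least 99.4% of these the Poisson probability of the recovered pileup matched the deposited −log10 p-value within 0.01. The background pileup ranged from 1.74 to 3.72 reads, and the least summit pileup listed at that background from 8 to 11 reads. A weak site can thus be absent from a shallow library without being closed, and an unlisted site was treated as not detected.

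Consensus regions were the union of overlapping peaks of all 12 libraries on chromosomes 1 to 19, X and Y, with presence meaning an overlap of at least 1 bp. Each region present in 1 to 11 libraries was tested between genotypes with the two-sided Fisher's exact test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Values per library were compared with two-sided exact permutation tests of the difference of means over all 924 splits of 6 against 6, whose smallest p is 0.00216. The clone is the independent unit, and an exact test of 2 clones against 2 cannot go below p = 0.333, so clone means are given beside genotype means. Within a genotype, an exact test of 3 libraries against 3 cannot go below p = 0.1. The construct was set beside 100 kb windows of the mouse chromosomes that held a peak in at least 1 library. Correlations carry p-values from 100000 permutations, or exact ones within a genotype.

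The samples, tests, gene lists and other settings were fixed before the data were examined. The 12 gene lists covered naive and general pluripotency, primed pluripotency, neural and ectoderm, mesoderm, endoderm, trophoblast, fibroblast and feeder, genes silent in embryonic stem cells, germline, housekeeping, Hox, and mouse Hprt with its neighbours on X. The text names every peak on the construct, up to 10 fully separated regions per direction with the highest median −log10 q-value, the 5 strongest regions shared by all 12 libraries, the first 3 members of each list, any list member with an unadjusted p under 0.05, and always Hprt, Pou5f1, Nanog and Sox2. A single item that this rule names is not reported here. Other names were chosen after their values were seen. The other settings were a −log10 q-value of at least 5, lists of equal length made of the strongest peaks of each library, peaks within 200 bp counted as 1, presence at 50% coverage, windows of 50 kb and 200 kb, windows of chromosome X, all windows, distances of 500 bp and 2 kb from gene ends, a block for the replicate number and leaving out each library. On simulated presence drawn from the 97889 real regions, the code found 200 of 200 seeded fully separated regions and called 0 of them after adjustment, and it recovered 600 of 600 simulated pileups. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.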

Results

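ATAC-seq peak lists were analysed from mouse embryonic stem cells with either synHPRT1 or synHPRT1R on chromosome X, to ask whether the human HPRT1 sequence and its reversed counterpart are accessible in these cells and how they compare with the rest of the genome. The 6 synHPRT1 libraries listed 48468, 46685 and 63563 peaks in clone 1 and 63704, 48954 and 38403 in clone 2. The 6 synHPRT1R libraries listed 58099, 52122 and 41737 peaks in clone 1 and 45904, 45731 and 44693 in clone 2. The means were 51629.5 ± 10047.3 and 48047.7 ± 5977.79 peaks (SD, n = 6 each), a difference smaller than the spread between libraries (two-sided exact permutation p = 0.468). The recovered background pileup, a measure of sequencing depth, averaged 2.67 ± 0.724 reads in synHPRT1 and 2.39 ± 0.431 in synHPRT1R (exact permutation p = 0.452). Over the 12 libraries the number of peaks followed this depth (Pearson's r = 0.849, permutation p = 0.00017; Spearman's rho = 0.846, permutation p = 0.00092). Without the 2 libraries farthest from the median depth, r was 0.715 (permutation p = 0.0152). Within synHPRT1, r was 0.897 (exact permutation p = 0.0236), and within synHPRT1R it was 0.681 (exact permutation p = 0.175). Because weak peaks enter a list only in deep libraries, counts of shared or missing peaks below are also given for lists of equal length where this matters.

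The synHPRT1 construct carried peaks in all 6 synHPRT1 libraries, and no peak on a construct sequence was listed in any of the 6 synHPRT1R libraries. Clone 1 had 7, 4 and 6 construct peaks and clone 2 had 1 in each library. A single region, positions 30283 to 31906 of the construct sequence, was open in all 6 synHPRT1 libraries. The genotype means were 3.33 ± 2.73 and 0 ± 0 peaks (SD, n = 6 each), and the listed numbers differed by more than the spread between libraries (two-sided exact permutation p = 0.00216, the smallest that 6 against 6 allows). The lists do not show whether reads were aligned to the reversed construct or whether peaks called on it were left out. In either case the 0 in synHPRT1R would have been fixed in advance, and this p would say nothing about its chromatin. Peaks covered 1928 ± 1067 bp of the construct in synHPRT1 and 0 bp in synHPRT1R (n = 6 each, exact permutation p = 0.00216). Over clones, the means were 5.67 ± 1.53 and 1 ± 0 peaks in synHPRT1 clones 1 and 2 (n = 3 each) and 0 in both synHPRT1R clones, and an exact permutation test of 2 clones against 2 cannot go below p = 0.333.

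The region at 30283 to 31906 spanned 1624 bp, and the fold at the summit of its strongest peak ranged from 4.86 to 7.28 over the 6 lists. The summit lay at 31078 in clone 1 replicate 2, at 31072 in clone 1 replicate 3, at 31079 in clone 2 replicate 1 and at 31074 in clone 2 replicate 3. In clone 1 replicate 1 it lay at 30666 and in clone 2 replicate 2 at 31254. This peak outranked 65.6 ± 15.2% of the peaks of its own list by fold (SD, n = 6), from 42.6% in clone 2 replicate 2 to 80.9% in clone 1 replicate 2. The other 9 construct regions were listed in clone 1 only. Of these, 39174 to 39535, 68061 to 68685, 70165 to 70513 and 91788 to 92304 appeared in 2 of its 3 libraries. The regions 19502 to 19789, 25661 to 25867, 43741 to 43925, 54623 to 55026 and 86987 to 87411 appeared in 1. The strongest of these 9 was 91788 to 92304, with a fold of 5.96 in clone 1 replicate 2, and the weakest peak, at 70173, had a fold of 2.89 in clone 1 replicate 3. Which part of HPRT1 or of the vector lies at any of these positions was not determined. The difference between the clones in the number of construct peaks had an exact permutation p of 0.1, the smallest that 3 against 3 allows. With a −log10 q-value of at least 5, as in lists of equal length, the construct mean fell to 1.67 peaks over synHPRT1. Clone 1 had 2.33 and clone 2 had 1. The genotype difference had the same p of 0.00216 (exact permutation, n = 6 each). This p could not change, since every synHPRT1 library kept a construct peak against a count of 0.

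**Figure D1:**
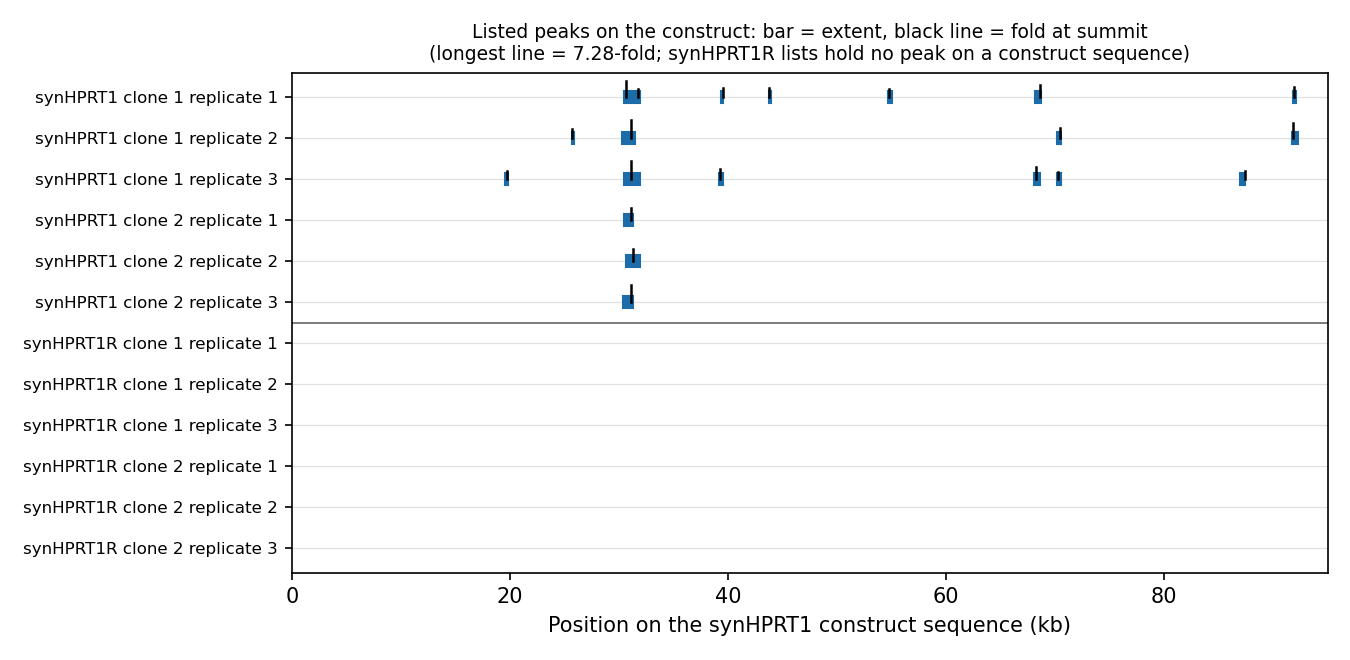
Peaks listed on the construct sequence in each of the 12 libraries (x axis, position in kb; bars, peak extent; black lines, fold at the summit, to a common scale). The 3 libraries of synHPRT1 clone 1 show 7, 4 and 6 peaks, those of clone 2 show 1 each at 30283 to 31906, and the 6 synHPRT1R rows are empty.

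Set beside the mouse genome in the deposited lists, the construct in synHPRT1 clone 1 was as rich in peaks as the richer 100 kb windows. In clone 2 it resembled windows with few peaks. In clone 1, 13.5 ± 7.53% of 21841 mouse windows had at least as many peaks as the construct, and in clone 2 81.2 ± 7.82% did (SD, n = 3 each). Over the windows of chromosome X alone, these shares were 3.77 ± 2.60% and 76.4 ± 9.44%. The richness of clone 1 rested in part on weak peaks, as its construct mean was 2.33 peaks at a −log10 q-value of at least 5. At that threshold the share over the 6 synHPRT1 libraries was 59.8 ± 23.5%, against 47.3 ± 37.7% in the deposited lists, and it was not split by clone. A mouse window held 2.36 ± 0.460 peaks in synHPRT1 and 2.2 ± 0.274 in synHPRT1R (mean and SD over 6 libraries). In the synHPRT1R libraries, which listed 0 construct peaks, 19.3 ± 3.55% of the windows had 0 peaks (n = 6), and on chromosome X 25.2 ± 3.88% of 1044 windows did. Windows without a peak in any of the 6 synHPRT1R libraries made up 5.77% of the 21841 windows and 9.10% of the 1044 on chromosome X. Over all 27234 mouse windows, those with no peak in any library included, their share was 24.4%. Setting the synHPRT1R construct beside these windows assumes that its 0 was measured, which the lists do not show. The share for synHPRT1R depended on the choice of windows: it was 35.3% when windows with no peak in any library were kept and 9.62% over windows with an end of a protein-coding gene. The length of the construct is not given in the sources used here, and its last listed peak ends at 92304.

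**Figure D2:**
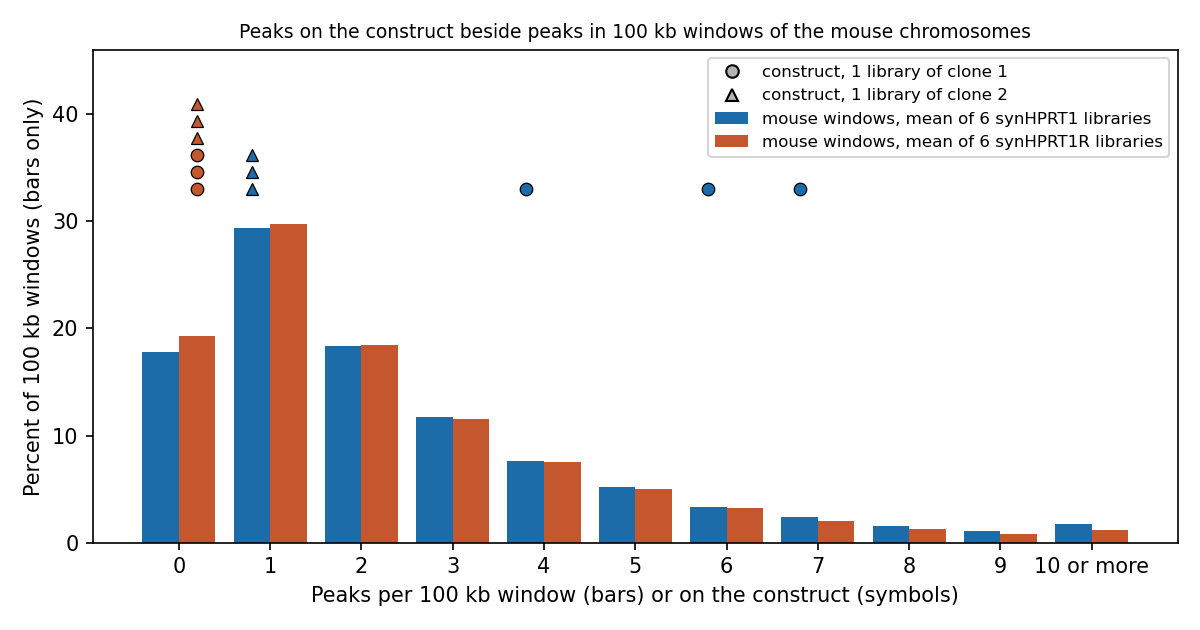
Peaks per 100 kb window of the mouse chromosomes (bars, percent of windows, mean of the 6 libraries of each genotype) with the number of peaks on the construct in each library (symbols, whose height has no meaning). Symbols of synHPRT1 clone 1 stand at 4, 6 and 7 peaks, those of clone 2 at 1 and those of synHPRT1R at 0.

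Across the mouse chromosomes the genotypes shared most of their open chromatin, and no region passed the test between them. Of 97889 consensus regions, 23285 (23.8%) were present in all 12 libraries and 26507 in only 1. Of the 74604 regions present in 1 to 11 libraries, 0 differed between genotypes by Fisher's exact test with Benjamini-Hochberg adjustment, and 164 had an unadjusted p under 0.05, 123 of them present more often in synHPRT1 and 41 more often in synHPRT1R. In lists of equal length this split was 92 to 95. With 6 libraries per genotype, an adjusted p under 0.05 would have needed at least 3230 fully separated regions, so a count of 0 does not rule out single regions that differ. A pair of libraries shared 60.8 ± 3.16% of peaks within a clone (12 pairs), 61.3 ± 2.74% between clones of a genotype (18 pairs) and 60.8 ± 2.54% between genotypes (36 pairs), as mean and SD over pairs.

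Fully separated regions, present in all 6 libraries of one genotype and in none of the other, numbered 8 for synHPRT1 and 6 for synHPRT1R. These counts depended on the setting: they were 3 and 6 at 50% coverage and 11 and 2 at a −log10 q-value of at least 5. Leaving out a library can raise them, because fewer libraries must match, so a rise alone shows no instability. Which genotype had more still changed: they were 51 and 8 without synHPRT1 clone 2 replicate 3, and 12 and 16 without synHPRT1 clone 2 replicate 1. The 8 open in synHPRT1 included a region at chromosome 3 108070231 to 108070819, 3240 bp from Ampd2, an AMP deaminase gene. Another lay at chromosome 16 23381186 to 23381437, 20836 bp from St6gal1, a sialyltransferase gene. The next lay at chromosome 5 134028400 to 134029206, 70542 bp from Castor2. Others lay within Yeats2 at chromosome 16 20176790 to 20177080, at the end of C330007P06Rik at chromosome X 36864133 to 36864764, and within Atp8a1 at chromosome 5 67831463 to 67832397. The remaining ones lay at chromosome 7 141451823 to 141452499, 464 bp from the ribosomal protein gene Rplp2, and at chromosome 14 111115067 to 111115691, 359863 bp from Slitrk6. The 6 open in synHPRT1R lay within Lingo2 at chromosome 4 35839833 to 35840066, within the protein kinase C gene Prkce at chromosome 17 86615479 to 86616070, and 8033 bp from Acsl3, an acyl-CoA synthetase gene, at chromosome 1 78649126 to 78649792. Distal ones lay 81052 bp from the water channel gene Aqp4 at chromosome 18 15308110 to 15308342, 383743 bp from Nr2f1 at chromosome 13 78582616 to 78583069 and 251357 bp from Diras2 at chromosome 13 52252383 to 52253018. Each had an unadjusted Fisher's exact p of 0.00216 and an adjusted p of 1. Their median −log10 q-values ran from 2.46 at Atp8a1 to 7.88 at Lingo2. When the lists were cut to equal length, 1 of the 8 and 2 of the 6 remained fully separated, and with a −log10 q-value of at least 5 the same numbers did.

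Clones of the same genotype differed at more regions than the genotypes did, as 3 libraries against 3 are more easily separated by chance. In synHPRT1, 306 regions were present in all 3 libraries of clone 1 and in none of clone 2, and 181 the other way. In synHPRT1R these numbers were 593 and 151. In lists of equal length they were 243 and 266 in synHPRT1 and 281 and 257 in synHPRT1R, so the excess for clone 1 in both genotypes depended on list length. By median rank of the −log10 p-value within each list, the strongest regions shared by all 12 libraries lay at chromosome 2 98666240 to 98667471, 1034568 bp from Lrrc4c, with a fold of 23.5 ± 0.333, and at chromosome 9 35305222 to 35305591, 29265 bp from Rpusd4, with a fold of 46.9 ± 0.617 (SD, n = 12). The next ones lay within Chl1 at chromosome 6 103649056 to 103649286, with 48.9 ± 0.807, 1140501 bp from Galc at chromosome 12 97061434 to 97061786, with 26.7 ± 0.605, and 32099 bp from Eea1 at chromosome 10 96077617 to 96077881, with 42.7 ± 0.816. Whether a blacklist or a filter on multi-mapping reads was applied is not given. These strongest signals therefore cannot be read as open chromatin from the lists alone, and the nearest genes only mark their place.

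At the gene level, cells of both genotypes showed open chromatin at most pluripotency genes and none near the ends of a list of genes taken as silent in embryonic stem cells. Nanog and Sox2, transcription factors that sustain the pluripotent state, had a peak within 1 kb of a gene end in 12 of 12 libraries. Pou5f1, which encodes Oct4, had one in 3 synHPRT1 and 3 synHPRT1R libraries, and in 12 of 12 libraries within 2 kb. Of 20 naive and general pluripotency genes, 15 had a peak in at least 10 libraries, and of 10 primed pluripotency genes 10 did, among them Fgf5, Otx2 and Dnmt3b in 12, 10 and 12 libraries. Of 10 genes taken as silent in embryonic stem cells, such as Alb, Ins2 and Cd3e, 0 had a peak near a gene end in any library. Against the 55.0% of other protein-coding genes with a peak in at least 10 libraries, the primed list was higher (two-sided Fisher's exact test, adjusted p = 0.0172 over 12 lists) and the silent list lower (adjusted p = 0.00408). The primed list lost this call at 500 bp from the gene ends (8 of 10, adjusted p = 0.220 by Fisher's exact test) and in lists of equal length (9 of 10, adjusted p = 0.0866), and the silent list kept its call in both. The naive and general list did not pass (Fisher's exact test, adjusted p = 0.153).

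The other lists did not pass this test at 1 kb from the gene ends. At 2 kb, the neural and ectoderm list (10 of 10) and the housekeeping list (14 of 15) passed, each with an adjusted p of 0.0218 by Fisher's exact test. Of 10 neural and ectoderm genes 9 had a peak in at least 10 libraries (adjusted p = 0.111 by Fisher's exact test), with Pax6 in 11, Sox1 in 6 and Neurog1 in 12. Of 10 mesoderm genes 5 did (0.762), with T in 8, Mesp1 in 11 and Tbx6 in 9. Of 10 endoderm genes 5 did (0.762), with Gata4 in 0, Gata6 in 10 and Sox17 in 12. Of 10 trophoblast genes 2 did (0.152), with Cdx2 in 12, Elf5 in 0 and Tfap2c in 6. Of 10 fibroblast and feeder genes, markers of cells that could accompany the stem cells, 3 did (0.215), with Col1a1 in 11, Col1a2 in 8 and Col3a1 in 0. Of 10 germline genes 4 did (0.433), with Dazl in 12, Mael in 9 and Sycp3 in 11. Of 15 housekeeping genes 12 did (0.153), with Actb in 0, Gapdh in 12 and Tbp in 12. Of 15 Hox genes 6 did (0.433), with Hoxa2 in 0 and Hoxa5 in 10. Of the 10 genes around Hprt on X 4 did (0.433), with Hprt in 0, Phf6 in 10 and Mospd1 in 12.

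The distance from the gene ends set several of these values. Over the whole gene with 1 kb on either side, Actb, Gata4, Elf5 and Esrrb each had a peak in 12 of 12 libraries, and housekeeping genes rose to 15 of 15 with a peak in at least 10 libraries (Fisher's exact test, adjusted p = 0.0126). By that measure and the same exact test, the naive and general list counted 18 of 20 and the neural and ectoderm list 10 of 10 (adjusted p = 0.0445 each), and the silent list 1 of 10 (adjusted p = 0.00607), the exception being Ptprc. Of 21887 protein-coding genes, 10536 (48.1%) had a peak near an end in all 12 libraries and 6921 (31.6%) in none.

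Gene lists did not separate the genotypes. The largest difference was in the germline list, with 60 ± 12.6% of its genes in synHPRT1 and 70 ± 8.94% in synHPRT1R (SD, n = 6 each, exact permutation p = 0.219, adjusted p = 1). Pluripotency genes had 86.7 ± 9.83% and 87.5 ± 8.22% (exact permutation p = 1). All 12 lists had an adjusted p of 1, and 0 members of any list had an unadjusted p under 0.05, so that 0 passed adjusted over the list alone. Over all 4430 genes with a peak in 1 to 11 libraries, 0 passed Fisher's exact test after Benjamini-Hochberg adjustment. The smallest p of that test with 6 against 6 is 0.00216. A call over this many genes would thus need many fully separated ones, so this 0 decides little. Without adjustment, 12 genes had a p under 0.05 by the same test, all 12 with more synHPRT1 libraries. They were C330007P06Rik on X, in 6 synHPRT1 and 0 synHPRT1R libraries; 1700019A02Rik, Cadps2, Glod5, Gm37116 and Lrrc1, in 5 and 0; and Bbc3, which encodes the apoptosis factor Puma, with Catsperg2, Fam178b, Lexm, Nrxn3 and Pcdha8, in 6 and 1. With lists of equal length, 12 genes had an unadjusted p under 0.05, 7 with more synHPRT1 and 5 with more synHPRT1R libraries, and 3 of them were among the 12 of the deposited lists. At a −log10 q-value of at least 5, 12 genes did, 11 with more synHPRT1 and 1 with more synHPRT1R libraries, and 2 of them were among the 12.

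**Figure D3:**
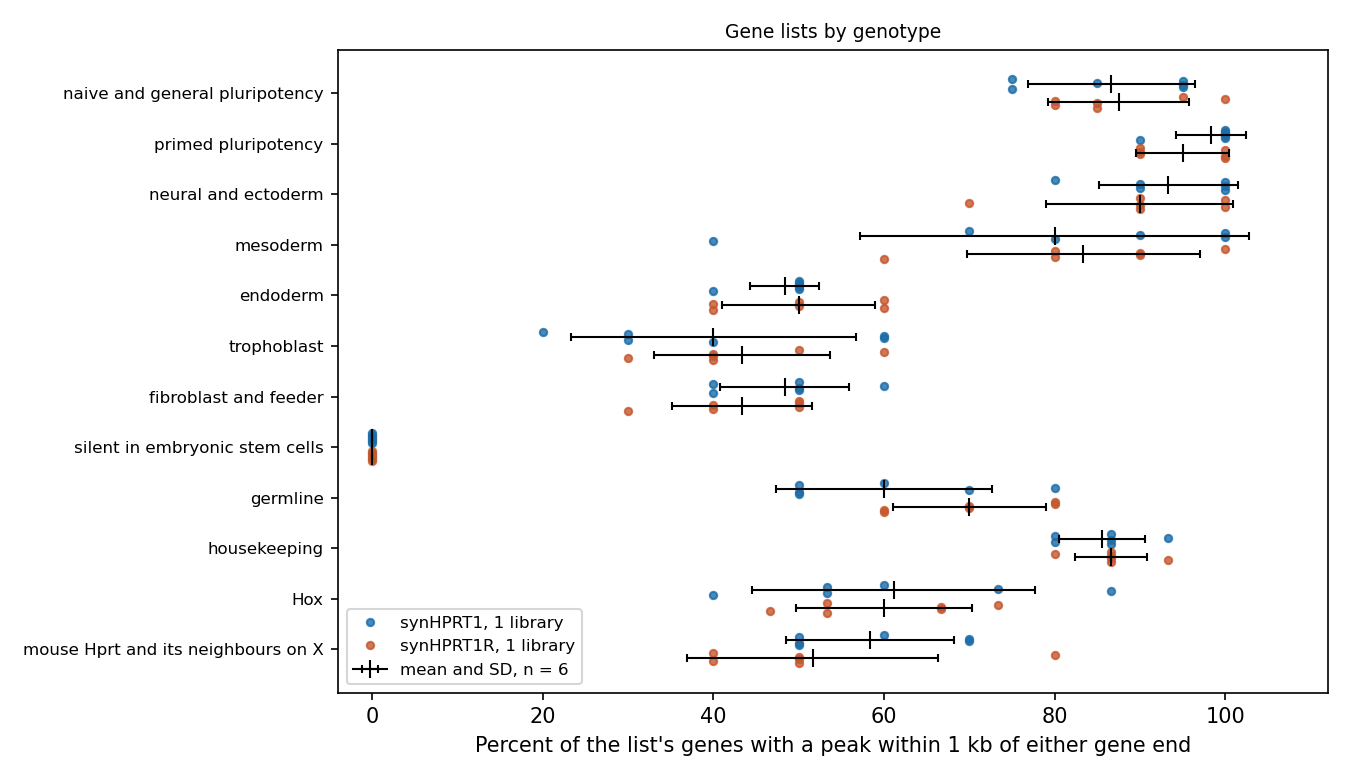
Percent of each gene list with a peak within 1 kb of either gene end (x axis) in each library (points) with the mean and SD of the 6 libraries of a genotype (black). The genotypes overlap in every list, and the list of genes silent in embryonic stem cells lies at 0 in all libraries.

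Mouse Hprt, the ortholog of the human gene in the constructs, had no peak in any of the 12 libraries. The gene lies at chromosome X 52988078 to 53021660 (gene ID 15452), inside a stretch without peaks in any library from 52962244 to 53052607, 90.4 kb long. On chromosome X, 551 of 2547 such gaps (21.6%) were at least as long, and the median gap was 25.9 kb. The flanking genes Gpc3 and Mospd1 had peaks near a gene end in 12 of 12 libraries and Phf6 in 10, and Plac1, a gene of placental development, in 0. Of the 22 regions within 500 kb of Hprt, 20 were present in some libraries only. Of these, 1 had an unadjusted p under 0.05, the region at 52961421 to 52962243, which ends 25835 bp below the start of Hprt and lies 4460 bp from Phf6. It was present in 5 of 6 synHPRT1 libraries, 3 of clone 1 and 2 of clone 2, and in 0 of 6 synHPRT1R libraries (two-sided Fisher's exact p = 0.0152, adjusted over the neighbourhood 0.303). In lists of equal length it was present in 3 and 0 libraries (Fisher's exact p = 0.182), and at a −log10 q-value of at least 5 in 4 and 0 (p = 0.0606).

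**Figure D4:**
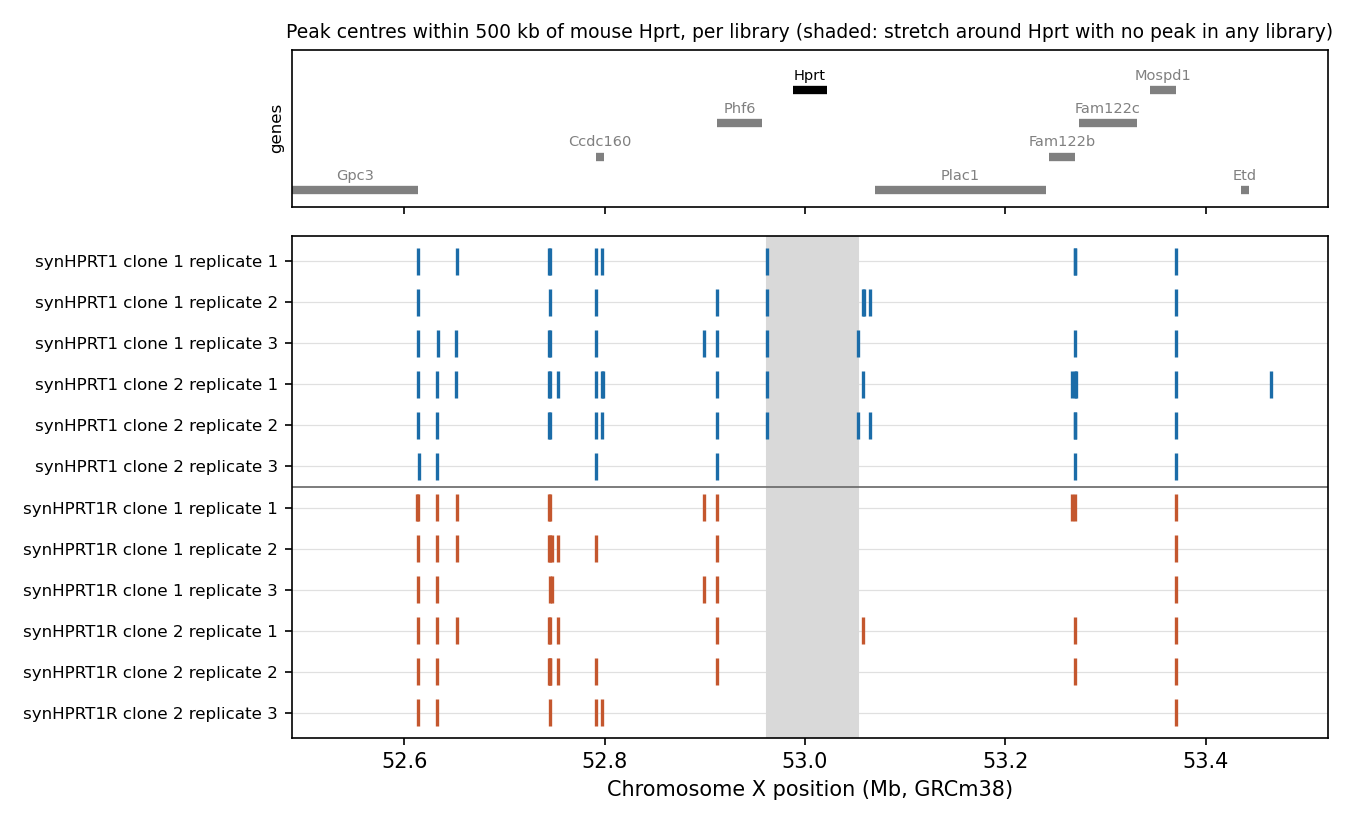
Centres of peaks within 500 kb of mouse Hprt on chromosome X in each library (ticks, not to scale in width; x axis, position in Mb) below the protein-coding genes of the region. The shaded stretch around Hprt, 90.4 kb long, holds no peak in any library, and the tick at its left edge appears in 5 synHPRT1 and 0 synHPRT1R libraries.

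The share of peaks on each chromosome did not separate the genotypes. Chromosome X held 2.92 ± 0.111% of peaks in synHPRT1 and 2.96 ± 0.0626% in synHPRT1R (SD, n = 6 each, exact permutation p = 0.416, adjusted p = 0.727), and chromosome Y 0.255 ± 0.0142% and 0.262 ± 0.0118%. The smallest p was that of chromosome 5, with 6.29 ± 0.0879% and 6.13 ± 0.0668% (exact permutation p = 0.00866, adjusted p = 0.182 over 21 chromosomes). Without synHPRT1 clone 1 replicate 1 this adjusted p was 0.0455 by the same exact permutation test, and it was 0.182 or more without any other single library.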

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

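The tests of depth, copy number and chance near Hprt, the test of the Hprt gap and the counts over other splits were chosen after the results were seen. In 78 groups of 6 libraries, 8 held a library far from the other 5, and chance gives about 1 in 20 groups.

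Libraries far from the rest of their genotype were as follows. Chromosome Y had 149 peaks in synHPRT1R clone 1 replicate 1, with the nearest library at 128. Chromosome 16 held 3.39% of the peaks of synHPRT1 clone 2 replicate 1, with the nearest at 3.31%. Chromosome 17 held 4.59% in synHPRT1 clone 2 replicate 2, with the nearest at 4.47%. Chromosome Y held 0.283% in synHPRT1 clone 1 replicate 2, with the nearest at 0.257%. In synHPRT1 clone 2 replicate 3, the library with the lowest background pileup (1.74 reads), 90% of primed pluripotency genes had a peak against 100% in the other synHPRT1 libraries, and 40% of endoderm genes against 50%. Neural and ectoderm genes stood at 70% in synHPRT1R clone 1 replicate 3, with the nearest library at 90%. Genes around Hprt stood at 80% in synHPRT1R clone 1 replicate 2, with the nearest at 50%. The mitochondrial genome, whose peaks entered no comparison, was listed as peaks in every library, with a highest fold per library between 1.22 and 1.59. These peaks covered 15457 to 16299 bp of it and the fold is against the local background. The fold thus does not show how far it stood above the rest of the genome. Whether its reads raised the background pileup used as depth was not tested.

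Construct peaks numbered 4 to 7 in clone 1 and 1 in clone 2 of synHPRT1, and the clone means were 2.33 and 1 at a −log10 q-value of at least 5 and in lists of equal length. The tables argue against sequencing depth as the cause, since the deepest clone 2 library had a background pileup of 3.72 reads, above the highest of clone 1 (3.16), and still 1 construct peak, and clone 2 replicate 2 (2.7) was deeper than clone 1 replicate 1 (2.03), which had 7. More copies of the construct in clone 1 may raise weak sites over the listing threshold, and the shared peak at 30283 to 31906 had a summit pileup over background of 16.0 ± 0.179 in clone 1 and 7.33 ± 2.13 in clone 2 (SD, n = 3 each), a ratio of 2.18 with a standard error of 0.366 (exact permutation p = 0.1, the smallest possible). At the shared peak the local background was 1.95 ± 0.0692 times the genome-wide one in clone 1 and 1 times in clone 2, and at 11 of the 13 other clone 1 peaks it stood at the genome-wide level, which a single copy and a pair of copies on X can both give, so copy number and accessibility cannot be told apart here. A difference between the clones in the chromatin of the construct stays open and was not tested.

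The region at chromosome X 52961421 to 52962243 was present in 5 of 6 synHPRT1 and 0 of 6 synHPRT1R libraries. At its lowest pileup over background in the synHPRT1 libraries that listed it, 5.07, it would have been listed at the depth of 6 of 6 synHPRT1R libraries. That test decides nothing about depth, since the same holds for synHPRT1 clone 2 replicate 3 (background 1.74, listing from 8 reads), where the region was absent. The difference had, in lists of equal length, a Fisher's exact p of 0.182, so depth stays open. Chance among the regions near Hprt also stays open, with an adjusted p of 0.303. An effect of the construct on the chromatin beside its integration site is a hypothesis that these data leave untested, since the position of that site is not given in the sources used here.

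Mouse Hprt had no peak in 12 of 12 libraries, while 15 of 15 housekeeping genes had a peak within the gene or 1 kb of it in at least 10. A candidate explanation is that mouse Hprt is absent from these cells. Of the peak-free gaps of chromosome X, 21.6% were at least as long as the one that holds Hprt, and of all protein-coding genes 4977 (22.7%) had no peak by the same measure, so an absent gene and a closed one cannot be told apart from peak lists, which record no reads below the threshold.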

How the results depend on the processing

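The windows with a gene end, the whole-gene measure, the block for the gene lists, the alternatives for single genes and every alternative for the Hprt neighbourhood were chosen after the data were seen. Depth sets a floor on what was listed, a pileup of 8 to 11 reads. Of all alternative values, 148 were taken as the same and 33 as moved. A tested value was the same on the same side of the threshold, a share within its spread, and a count within a fixed ratio of the main count. Many could not move, such as counts of 0 called regions, or shares of windows in a genotype when a library of the other was left out. The tally thus does not measure stability. Construct peaks fell from 3.33 to 1.67 with a −log10 q-value of at least 5 and in lists of equal length. Their p cannot show stability, since every synHPRT1 library kept a construct peak against a count of 0. The share of windows with 0 peaks in synHPRT1R was 35.3% with all windows kept, 25.2% on chromosome X, 27.7% in 50 kb windows, 11% in 200 kb windows and 9.62% in windows with a gene end, which follows from how many windows hold peaks. With a −log10 q-value of at least 5, fully separated regions numbered 11 for synHPRT1 and 2 for synHPRT1R, regions separating the synHPRT1 clones 267 and regions near Hprt with an unadjusted p under 0.05 0. The last was also 0 in lists of equal length. With 50% coverage, 3 regions were fully separated for synHPRT1 and 6 for synHPRT1R, so that synHPRT1 no longer had more. Except for the shares of windows, the cause was not tested.

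Without each library in turn, fully separated regions ranged from 9 to 51 for synHPRT1, the highest without synHPRT1 clone 2 replicate 3, and from 6 to 16 for synHPRT1R, the highest without synHPRT1 clone 2 replicate 1. There synHPRT1R had more (16 against 12), as without synHPRT1 clone 1 replicate 3 (13 against 10). Regions separating clones ranged from 1125 to 1762 in synHPRT1 and from 1507 to 2663 in synHPRT1R. Regions separating clones rose each time, and fully separated regions rose or stayed, because fewer libraries must match. Chromosomes that differed ranged from 0 to 1.

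No pairing of the libraries by replicate number was seen: same-numbered libraries had a mean correlation of deviations of -0.00188 and others 0.000949. Single pairs ranged from -0.0356 to 0.0344 and from -0.0336 to 0.0407, so a weak pairing is not excluded. With the replicate block, construct peaks differed by 3.33 (exact permutation p = 0.00926), covered length by 1928 bp (p = 0.00926) and peaks per library by 3581.83 (p = 0.519). The block changed no call, as 0 consensus regions and 0 gene lists passed. For the consensus regions this decides little, since the smallest exact p with the block was 0.00926 over 74604 tested regions.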

Other observations

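The tests in this part were chosen after the results were seen, as were the genes named. Some regions were present in all libraries of 3 clones and absent from all 3 libraries of the fourth. In synHPRT1R clone 2 there were 40 such regions, against 7 in synHPRT1R clone 1, 5 in synHPRT1 clone 1 and 5 in synHPRT1 clone 2. Among the 40 were regions within Sel1l2 at chromosome 2 140389489 to 140390124, within Pstpip2 at chromosome 18 77879150 to 77879590 and 56692 bp from Nog, which encodes the BMP antagonist noggin, at chromosome 11 89243257 to 89243946, with median folds of 7.99, 7.65 and 5.40 over the libraries that had them. In lists of equal length the counts were 20 in synHPRT1R clone 2, 7 in synHPRT1R clone 1, 23 in synHPRT1 clone 1 and 11 in synHPRT1 clone 2, so synHPRT1R clone 2 no longer had the most.

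The 14 regions that fully separated the genotypes were set beside other groupings of the same libraries. Of 100 splits of the 12 libraries into 6 and 6, the real one included, 18 gave as many, and the highest other split gave 66, so chance cannot be excluded. That split put the 6 longest lists together, 4 of synHPRT1 and 2 of synHPRT1R, and a count several times the real one points to a structure of the samples. In lists of equal length the genotypes were separated at 16 regions, and 1 of 100 splits, the real one, gave as many. The highest other split gave 15, so the margin was narrow. Of the regions separated in the deposited lists, 1 of 8 and 2 of 6 remained so there. Splits of single libraries also break up the clones, which are the independent unit, so chance is not excluded in lists of equal length either. Each of the other pairings of the 4 clones gave 6 regions in lists of equal length, and 2 and 5 in the deposited lists. With 3 pairings of the clones, no share under 0.05 can be reached. A simulation without any difference between libraries gave 7 fully separated regions of 97889. It drew each region of the deposited lists independently in each library, without the real differences in list length. Its count is therefore no reference for the 14 or the 16 regions.

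Within genotypes, 10 splits of 6 libraries are too few for a share under 0.05. In synHPRT1, 487 regions separated the clones, 8 of the 10 splits gave as many and the highest other split gave 1680. In synHPRT1R, 744 regions separated them, 4 of the 10 splits gave as many and the highest other split gave 975.

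Construct peaks of synHPRT1 were carried over to the depth of the synHPRT1R libraries as a check of what these could have listed. With its summit pileup scaled to their background, the peak at 30283 to 31906 passed the lowest listed −log10 p-value in 36 of 36 combinations of a synHPRT1 and a synHPRT1R library. Of the 20 construct peaks listed in synHPRT1, between 18 and 20 passed at the depth of each synHPRT1R library. This count decides nothing about the weaker sites, since it covers only peaks that had been listed. Apart from the shared region, each construct region was missing from several synHPRT1 libraries, the deepest of them included. The check thus speaks only for a peak as strong as that at 30283 to 31906. On the reversed sequence such a peak would have been listed at these depths under certain conditions. Reads must have been aligned to the reversed construct and peaks called on it kept in the lists, neither of which the lists show.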
